A study of Homo sapiens with 6 samples.

How the data were processed

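RNA from the hepatocellular carcinoma cell line MHCC-97H was sequenced in 6 libraries, 3 labelled as control (Ctrl) and 3 labelled as overexpressing SMS2 (SMS2). SMS2 is the protein encoded by *SGMS2*, sphingomyelin synthase 2. The series text speaks of a pair of cell lines; libraries of another line were not analysed here. Groups and replicate numbers came from the sample titles. The genotype field of SMS2 replicates 2 and 3 names SMS3 and SMS4 in place of SMS2, which disagrees with their titles, and the titles were followed. The labels call the control genotype wild type and do not say whether a vector was used. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

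The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), 1 value per gene symbol and library, per the file headers. Per the submitters' processing notes, HISAT2, StringTie and the build hg18 were used; their versions, their order and the annotation are not given in the sources used here. Per the labels' protocols, libraries were made with the NEBNext Ultra RNA kit. No coordinates are given, because an annotation of that build was not used here. Symbols were matched to GENCODE release 29 for gene type, transcript length and GC content only; 82.3% of the symbols tested matched.

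The deposited FPKM files have features that could affect the measurements. No file holds a value of 0: a symbol is either listed above 0 or not listed. Of 26713 symbols listed in at least 1 file, 16120 were listed in all 6. Between 36.2% and 37.3% of the symbols at 1 FPKM or more in a library had exactly the value of another symbol. Neighbouring or overlapping genes may have been given 1 value, but positions were not examined, and some equal values can be a coincidence. Which symbols shared a value could differ between files. Symbols that were listed in all 6 files and shared their value with the same symbols, or none, in each file are called stable loci, and each shared value was then counted 1 time. Strand use in counting is not given in the sources used here, so antisense partners cannot be told apart.

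Read depth is not stated. Ratios of low values (under 0.1 FPKM) between libraries lay on ratios of whole numbers up to 6, within 0.01 on the log2 scale, in 57.1% to 60.7% of cases, against 4.63% to 5.37% when the scale was shifted. The most frequent ratio put the libraries at 0.933 to 1.04 times the depth of Ctrl replicate 1. The search covered only ratios near 1, and depths that differ by a ratio of small whole numbers would give the same steps. A larger difference in depth between libraries or groups is therefore not excluded. Absolute depth is unknown, and no counting interval is given.

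The planned test was limma on log2(FPKM + 1), with a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. Unlisted symbols were entered as 0, and the 15323 symbols with a mean of at least 1 FPKM over all libraries were tested. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Folds are ratios of mean FPKM. Of the symbols tested, 2025 were not listed in at least 1 file and 3777 more changed partners between files. For this reason the counts over all genes and over the called lists are also given for the 8047 stable loci tested, an alternative chosen after the data were examined. For 1080 of the 3777, no tested symbol listed in all files shared their value in more than 1 file, and equal values in 1 file can be a coincidence.

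Before the data were examined, 24 gene lists were fixed and tested with limma's camera (preset inter-gene correlation 0.01, adjusted over the lists). The list of mitochondrially encoded genes had 0 listed members and was not tested, which left 23. Named genes were *SGMS2*, *SGMS1*, *SAMD8* and 4 PI3K subunit genes; the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, leaving out small, unnamed and pseudogene symbols; up to 2 risen and 2 fallen members per list; and the most abundant member of the cell-type and RNA-quality lists. The exclusion of unnamed symbols missed the clone-named CTB-31N19.3, which is among the 8 falls. Not every gene that this rule names is reported here. A set of 12 rises and 12 falls by the same rule among stable loci, and further list members named as examples, were chosen after the data were examined.

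Alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, 3 scalings between libraries, the spread estimate, array weights, an estimated inter-gene correlation, fry, symbols listed in all files, a replicate block, leaving out each library and a minimum change of 1 on the log2(FPKM + 1) scale. Those added later were shared values counted 1 time, stable loci, and removal of trends with transcript length and GC. No symbol had more than 1 row in a file, so the planned choice between such rows did not arise. On simulated values for stable loci (7991 genes), changes of 0.5, 1, 2 and 3 on the log2 scale were recovered for 73.5%, 98%, 100% and 100% of genes, and 6.48% of calls were of unchanged genes. For all symbols (14971 genes) recovery was 20%, 52.1%, 64.6% and 87.2%, and 12.6% of calls were of unchanged genes, above the nominal rate. The simulation drew genes independently with the fitted spread and changed a far smaller share of genes than was called in the data. These percentages hold for that setting and may differ in the data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 were used.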

Results

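The transcriptome of MHCC-97H cells, a human hepatocellular carcinoma line, was measured by RNA sequencing in 3 control and 3 SMS2-overexpressing libraries. SMS2, the product of *SGMS2*, makes sphingomyelin from ceramide. Each library listed 20221 to 21212 gene symbols. Low values put the libraries at 0.933 to 1.04 times the depth of the first control library, in a search limited to ratios near 1. Absolute depth is unknown. The summed FPKM was 937353 to 955440 in the control libraries and 846173 to 873717 in the SMS2 libraries. A value shared by several symbols entered this sum for each of them, and unlisted symbols added nothing. The sum therefore depends on the naming of loci and is not a library total. Over symbols listed in all files, log2 values correlated at 0.941 to 0.951 within groups and 0.918 to 0.929 between groups, across genes, which are not independent replicates. The file headers of the 3 control libraries carried a tag that 0 SMS2 headers carried, so a batch, if the tag marks one, held libraries of 1 group only and cannot be told apart from the groups.

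The overexpressed gene was examined first. *SGMS2* rose from 3.54 ± 0.239 FPKM (SD, n = 3) in control libraries to 38.4 ± 1.47 FPKM (SD, n = 3) in SMS2 libraries, a 10.9-fold difference. Its log2 change was 3.12 ± 0.06 (SE; limma adjusted p = 3.02e-05), and the 3 SMS2 values lay above the 3 control values. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. *SGMS1*, the paralog at the Golgi, was at 6.43 ± 0.193 FPKM in control and 6.38 ± 0.157 FPKM in SMS2 libraries (SD, n = 3 each; limma adjusted p = 0.923). *SAMD8*, a related ceramide phosphoethanolamine synthase gene, rose 1.42-fold (limma adjusted p = 0.0105), a call lost with no filter on low values and with a minimum of 5 FPKM.

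**Figure D1:**
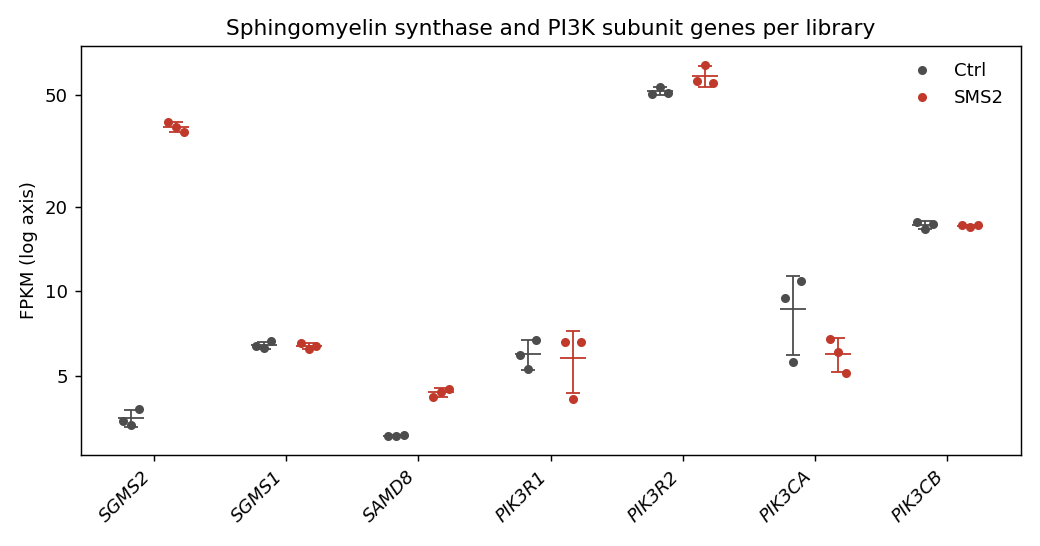
FPKM (log axis) of 3 sphingomyelin synthase family genes and 4 PI3K subunit genes; points are libraries, horizontal marks are group means and bars are SD (n = 3). *SGMS2* was 10.9-fold higher in SMS2 libraries, and the PI3K subunit genes did not pass the test.

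Other genes of sphingolipid metabolism went in both directions. Of 38 members tested, 4 rose, 6 fell and 28 did not pass (adjusted over the list alone, 6 rose and 8 fell), and the list did not differ from other genes (camera adjusted p = 0.453). When values were rescaled to a common sum, 7 rose and 5 fell. *SGPL1*, the lyase that degrades sphingosine 1-phosphate, fell from 7.21 ± 0.383 to 3.85 ± 0.195 FPKM (SD, n = 3). The ceramide synthase *CERS2* fell by 0.46 on the log2 scale and the acid sphingomyelinase *SMPD1* by 0.38. The sphingosine 1-phosphate receptor *S1PR5* rose 3.84-fold from a low level of 0.531 ± 0.116 FPKM (SD, n = 3). *S1PR1* rose 1.81-fold and *SGPP2* fell by 0.55 on the log2 scale. The *S1PR1* call was lost without each of the 6 libraries in turn (limma adjusted p up to 0.098). That of *SGPP2* was lost without each except Ctrl replicate 3 (limma adjusted p up to 0.0831). A fit without 1 library has fewer degrees of freedom, so a call near the threshold can be lost whichever library is left out. Here and below, such a loss need not mean dependence on that library.

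The series title names p85/p110, the regulatory and catalytic subunits of PI3K, so their genes were compared. RNA levels do not measure subunit protein, p85/p110 binding or PI3K activity, which were not examined here. *PIK3R1* (log2 change -0.06 ± 0.19), *PIK3CA* (-0.43 ± 0.25), *PIK3CB* (-0.01 ± 0.04) and *PIK3R2* (0.18 ± 0.07; SE) did not pass the test, with limma adjusted p of 0.851, 0.282, 0.919 and 0.155. *PIK3R2*, which shared its value with *IFI30*, passed when values were rescaled to a common sum (adjusted p = 0.0246). Of 44 genes of the PI3K-AKT-mTOR list, 3 rose, 6 fell and 35 did not pass (adjusted over the list alone, 3 rose and 4 fell; camera adjusted p = 0.402). When values were rescaled to a common sum, 5 rose and 3 fell. *EIF4EBP1*, a translation repressor controlled by mTOR, fell from 136 ± 7.53 to 67.2 ± 3.08 FPKM, and *DEPTOR*, an mTOR inhibitor, fell from 11.3 ± 1.41 to 3.16 ± 0.927 FPKM (SD, n = 3 each). *IRS1* rose 1.73-fold and *EIF4E* 1.37-fold, calls lost without each library except SMS2 replicates 1 and 3 for *IRS1* (limma adjusted p up to 0.0886) and except SMS2 replicate 2 for *EIF4E* (up to 0.0891). Of 25 FOXO target genes, 5 rose, 2 fell and 18 did not pass (adjusted over the list alone, 7 rose and 4 fell; camera adjusted p = 0.823; the median and mean were below 0 while camera gave the upward direction). Among them *SOD2* rose 5.74-fold and *CITED2* 1.83-fold, while *BBC3* fell by 1.20 and *IGFBP1* by 0.64 on the log2 scale. The *IGFBP1* call was lost without each library except Ctrl replicate 3 (limma adjusted p up to 0.09).

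Across the transcriptome, 3718 of 15323 symbols passed limma's test at an adjusted p of 0.05, with 1800 higher and 1918 lower in SMS2 libraries. Of these, 270 rose and 169 fell by at least 1 on the log2(FPKM + 1) scale, and 395 and 207 by at least 1 with a pseudocount of 0.1. Among stable loci, 3165 of 8047 passed, with 1625 higher and 1540 lower, and 119 rose and 93 fell by at least 1 on the log2(FPKM + 1) scale. Rescaling to a common sum moved the median of all genes to 0.12 on the log2 scale. The share of calls that were higher went from 48.4% to 70.9%. As that sum counts shared values repeatedly, the shift may partly reflect the naming of loci. The count was 2234 without Ctrl replicate 2 and 2450 without Ctrl replicate 1. Groups did not overlap for 45.7% of symbols tested, against 10% by chance for 3 against 3.

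The planned rule for the largest changes named 16 genes, and 0 of them were stable loci. Of the 16, 13 were not listed in at least 1 file. *DDIT3*, which encodes the stress factor CHOP, was listed at 457, 325 and 457 FPKM in the control libraries and was not listed in the SMS2 libraries. *GRINA*, *MAGOH*, *IRF3*, *HSBP1L1*, *METTL5* and *SH3GLB2* were likewise listed in the control libraries only, and *KDELR3*, *ANKZF1*, *GON4L*, *YY1AP1* and *ANKRD34A* in the SMS2 libraries only. *GON4L* and *YY1AP1* had the same values and are 1 measurement. *C1orf189* was unlisted in 2 control libraries. The other 3 changed partners between files: *SEMA4A*, at 537 to 557 FPKM in SMS2 libraries, had the value of *LMNA* there, *KIAA1024* that of *TMED3*, and the clone-named transcript CTB-31N19.3 that of *METTL9* in control libraries. No fold is given for these genes.

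Among stable loci, the largest rises on the log2(FPKM + 1) scale were of *MT1X*, a metallothionein gene (31.5-fold, from 0.829 ± 0.413 to 26.2 ± 3.44 FPKM; SD, n = 3), *HIST1H4H*, a histone gene (12.1-fold), *SLC2A3*, which encodes the glucose transporter GLUT3 (39.9-fold, from 0.267 ± 0.0443 to 10.7 ± 1.34 FPKM; SD, n = 3), and *SGMS2*. *MT1X* has closely related gene copies and shared its value with a pseudogene, so its level is uncertain. *CDKN1C*, a cyclin-dependent kinase inhibitor gene, rose 11.9-fold, *PTHLH*, encoding parathyroid hormone-related protein, 8.66-fold, and *NDRG1* 7.9-fold, from 50.5 ± 8.65 to 399 ± 46.2 FPKM (SD, n = 3). *PDGFB*, *CLDN2*, *CST1*, *SOD2* and the heat shock gene *HSPA1A*, which shared its value with *HSPA1B*, rose between 5.62-fold and 26.2-fold. The largest falls were of *CHAC1* (log2 change -2.20 ± 0.15), *ATF3* (-2.11 ± 0.09), *AKNA* (-2.02 ± 0.12), *SAR1B* (-2.01 ± 0.06) and *GDF15* (-1.99 ± 0.12; SE). *ITPKA*, *UNC5B*, *PCK2*, *SLC6A9*, *NUPR1*, *LGALS2* and *VIL1* fell by 1.62 to 1.92 on the log2 scale. The limma adjusted p of these 24 genes among stable loci was at most 0.00355.

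Genes of the ER stress and amino acid response were lower as a list. Of 38 members, 21 were called lower, 8 rose and 9 did not pass (adjusted over the list alone, 23 lower and 8 higher). The median log2 change was -0.74 (camera adjusted p = 9.58e-06, and 0.176 with an estimated correlation). The 21 include *DDIT3*, which was not listed in the SMS2 libraries. *ATF4* itself fell from 421 to 264 FPKM, and *ASNS*, *TRIB3*, *PHGDH*, *SESN2* and *NUPR1* fell by 2.05, 1.99, 1.21, 1.28 and 1.77 on the log2 scale. The 8 that rose included ER chaperone and folding genes: *SDF2L1* rose 1.55-fold and *HSP90B1* 1.45-fold. Among stable loci 16 of 28 fell and 6 rose (camera adjusted p = 0.000528).

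**Figure D2:**
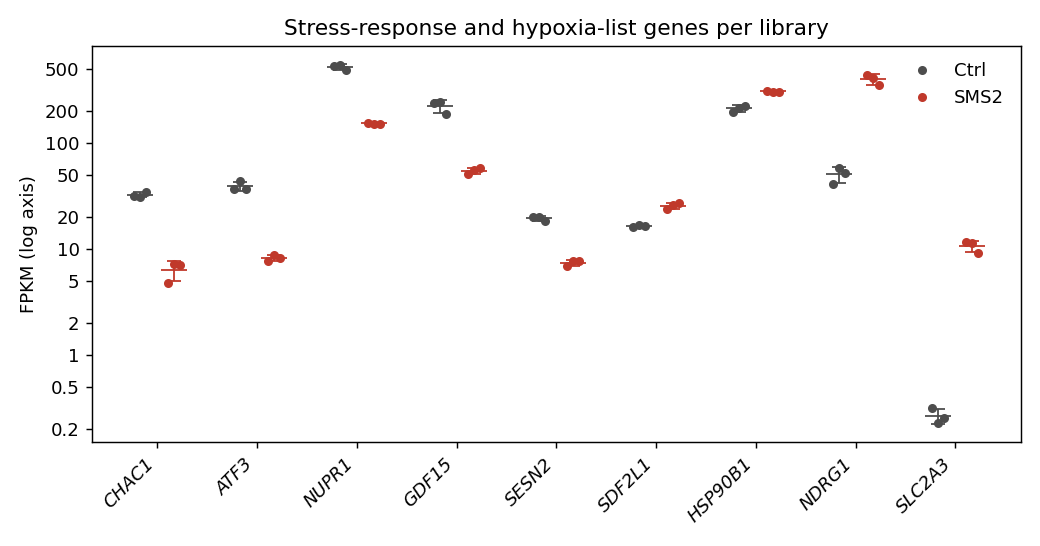
FPKM (log axis) of stress-response and hypoxia-list genes; points are libraries, horizontal marks are group means and bars are SD (n = 3). *CHAC1*, *ATF3*, *NUPR1*, *GDF15* and *SESN2* were lower in SMS2 libraries, and *SDF2L1*, *HSP90B1*, *NDRG1* and *SLC2A3* were higher.

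Genes of glycolysis and hypoxia were higher. Of 36 members, 16 rose, 0 fell and 20 did not pass (adjusted over the list alone, 20 rose and 1 fell; camera adjusted p = 2.48e-06; adjusted p = 0.176 with an estimated correlation). Besides *SLC2A3* and *NDRG1*, *ADM* rose by 2.06 ± 0.09, *P4HA2* by 1.21 ± 0.16 and *VEGFA* by 0.52 ± 0.06 (log2, SE). *ANGPTL4* was listed at 78.9 to 104 FPKM in SMS2 libraries, at 6.09 and 5.53 FPKM in 2 control libraries and not listed in Ctrl replicate 1. Its call was lost without any 1 of the SMS2 libraries (limma adjusted p up to 0.0596).

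Mesenchymal and EMT markers were higher, with 18 of 33 risen and 2 fallen (adjusted over the list alone, 19 and 2; camera adjusted p = 1.69e-07; adjusted p = 0.176 with an estimated correlation). The integrin gene *ITGA5* rose by 1.34 ± 0.06, *MMP2* by 1.12 ± 0.07, *COL6A3* by 1.61 ± 0.08 and the transcription factor gene *SNAI1* by 0.80 ± 0.11 (log2, SE). *LOX* was at 9.37 to 10.1 FPKM in SMS2 libraries, and not listed in 1 control library. *S100A4*, whose value was shared with other S100 genes, fell from 6062 ± 130 to 3300 ± 143 FPKM (SD, n = 3), a call lost under quantile normalization. *CTGF* fell by 0.75 on the log2 scale. Epithelial markers went both ways, with 6 risen, 6 fallen and 13 not passing of 25 (adjusted over the list alone, 7 and 8; 8 and 3 when rescaled to a common sum; camera adjusted p = 0.998; the median was below 0 and the mean above). *KRT19* rose 2.19-fold and *KRT7* 2.09-fold, and *PKP3* fell by 0.78 and *MARVELD2* by 0.66 on the log2 scale. The *MARVELD2* call was lost without Ctrl replicate 1 or 2 or SMS2 replicate 2 or 3 (limma adjusted p up to 0.0657).

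NF-kB and cytokine genes were higher, with 15 of 30 risen and 3 fallen (adjusted over the list alone, 18 and 5; camera adjusted p = 0.00035; adjusted p = 0.266 with an estimated correlation). When values were rescaled to a common sum 18 rose and 1 fell. *BIRC3*, an inhibitor of apoptosis gene, rose 6.21-fold, and *PTGS2*, *IL1B* and *TNFAIP3* rose by 2.33, 1.41 and 1.07 on the log2 scale. *NFKB1* and *NFKB2* fell by 0.44 and 0.38, the *NFKB2* call being lost without each library except Ctrl replicate 3 (limma adjusted p up to 0.0987). Of 32 interferon-stimulated genes, 11 rose, 1 fell and 20 did not pass (adjusted over the list alone, 11 and 1; camera adjusted p = 0.00438; adjusted p = 0.176 with an estimated correlation). *SAMD9* rose 3.17-fold and *IFI27* 2.43-fold, the latter not called without Ctrl replicate 1 (adjusted p = 0.0534), while *IFI35* fell by 0.68 on the log2 scale.

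Lists of proliferation genes were higher by small amounts. Of 48 G1/S genes, 15 rose, 1 was called lower and 32 did not pass (adjusted over the list alone, 18 and 2; camera adjusted p = 0.0038; adjusted p = 0.525 with an estimated correlation). The cyclin E gene *CCNE1* rose 1.78-fold and *ORC1* 1.83-fold, the latter call lost without Ctrl replicate 1 or 2 or SMS2 replicate 2 or 3 (limma adjusted p up to 0.0757). The member called lower, *RFC4*, was not listed in the SMS2 libraries. When values were rescaled to a common sum 23 of the 48 rose. Of 49 G2/M genes, 14 rose, 4 fell and 31 did not pass (adjusted over the list alone, 20 and 4; camera adjusted p = 0.0154; adjusted p = 0.176 with an estimated correlation). When values were rescaled to a common sum 21 rose and 2 fell. *ANLN* rose 1.75-fold and *KIF11* 1.76-fold, and *CENPA* and *CCNB1* fell by 0.86 and 0.39 on the log2 scale; the *KIF11* call was lost without the same 4 libraries as that of *ORC1* (up to 0.0603). MYC and growth targets did not differ as a list, with 2 risen, 4 fallen and 30 not passing of 36 (adjusted over the list alone, 2 and 4; camera adjusted p = 0.136; 0.0211 with no filter on low values; 4 risen and 3 fallen when rescaled to a common sum): *GNL3* and *NOLC1* rose 1.36-fold and 1.39-fold, and *RRP12* and *PUS1* fell by 0.55 and 0.54 on the log2 scale. The *NOLC1* call was lost without each library except Ctrl replicate 3 (limma adjusted p up to 0.101), and that of *PUS1* without Ctrl replicate 3 or any SMS2 library (up to 0.0762).

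Hepatocyte genes were lower, with 7 of 33 fallen and 1 risen (adjusted over the list alone, 7 and 1; camera adjusted p = 0.00878; adjusted p = 0.176 with an estimated correlation). Albumin (*ALB*) fell from 114 to 48.1 FPKM, *AMBP* by 1.31 on the log2 scale, and *ADH1B*, which shared its value with other ADH1 genes, from 264 ± 9.85 to 65.6 ± 9.7 FPKM (SD, n = 3). *HPD* rose 1.76-fold, a call lost without SMS2 replicate 2 or 3 (limma adjusted p up to 0.0697). Liver cancer and progenitor markers did not differ as a list (9 risen, 4 fallen and 14 not passing of 27; adjusted over the list alone, 9 and 4; camera adjusted p = 0.146), but were called under quantile normalization (adjusted p = 0.0224). *H19* rose 2.15-fold, and *KLF4* and *S100P* fell by 0.76 and 0.56 on the log2 scale.

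Cholesterol synthesis genes were higher, with 8 of 25 risen and 2 fallen (adjusted over the list alone, 10 and 2; camera adjusted p = 0.0201; adjusted p = 0.457 with an estimated correlation). *SQLE* rose 1.9-fold, while *TM7SF2* and *LSS* fell by 0.78 and 0.40 on the log2 scale. Under quantile normalization 5 rose and 2 fell. The list was not called among stable loci (adjusted p = 0.0593), without Ctrl replicate 1 (0.0563) or without SMS2 replicate 1 (0.066). Its median log2 change was 0.296 in the main test and 0.363 among stable loci. Fatty acid and glycerolipid genes went both ways, with 6 risen, 5 fallen and 28 not passing of 39 (adjusted over the list alone, 6 and 5; camera adjusted p = 0.791). *LPCAT1* rose 1.86-fold and *ELOVL6* 1.91-fold, and *ME1* and *CHPT1* fell by 0.58 and 0.55 on the log2 scale, the *ME1* call being lost without Ctrl replicate 1 or 2 or SMS2 replicate 2 (limma adjusted p up to 0.0553).

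Ribosomal protein genes were lower, with 36 of 67 fallen and 0 risen (adjusted over the list alone, 42 and 0; camera adjusted p = 2.57e-11; adjusted p = 0.176 with an estimated correlation). Under quantile normalization 18 fell and 2 rose, and 21 fell and 0 rose when values were rescaled to a common sum. The median log2 change was -0.29, and -0.13 relative to all genes under quantile normalization. *RPS29* fell from 1406 ± 59.8 to 781 ± 73.4 FPKM and *RPS9* from 593 ± 46.3 to 384 ± 3.5 FPKM (SD, n = 3 each). Of 51 nuclear genes of oxidative phosphorylation, 15 fell, 2 rose and 34 did not pass (adjusted over the list alone, 16 and 2; camera adjusted p = 0.00121; adjusted p = 0.176 with an estimated correlation). *NDUFA9* and *NDUFB1* fell by 0.81 and 0.54 on the log2 scale, and *SDHA* and *NDUFB3* rose 1.38-fold and 1.32-fold, the *NDUFB3* call being lost without each library except Ctrl replicate 3 (limma adjusted p up to 0.122). Under quantile normalization the list was not called (adjusted p = 0.107), and when values were rescaled to a common sum 8 fell and 5 rose.

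Lists on p53 targets and apoptosis (5 risen, 4 fallen and 31 not passing of 40; adjusted over the list alone, 5 and 4) and on ERK feedback and immediate early genes (4 risen, 9 fallen and 18 not passing of 31; adjusted over the list alone, 6 and 9; 8 and 6 when rescaled to a common sum) did not differ from other genes (camera adjusted p = 0.791 for both). In the ERK list *FOS* rose 3.34-fold and *NR4A1* 1.98-fold, and *AREG* fell by 1.26 on the log2 scale. The *AREG* call was lost without Ctrl replicate 1 or any SMS2 library (limma adjusted p up to 0.0671). In the p53 list *BIK* rose 2-fold, a call lost without each library except Ctrl replicate 3 (limma adjusted p up to 0.0735). Other p53 list members given above were *BIRC3*, which rose, and *BBC3* and *SESN2*, which fell.

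Markers of other cell types and of RNA selection were examined beside these groups. Of 5 blood cell markers tested, 2 were called lower, but *CD79A* had the value of the ribosomal protein gene *RPS19* and *CD68* shared values with *EIF4A1* and other symbols. Of 4 fibroblast and endothelial markers, *LYVE1* (0.603 to 2.41 FPKM) and *KDR* (1.12 to 2.44 FPKM) rose from low levels, and the most abundant, *PDGFRA*, was at 23.9 ± 4.1 and 22.5 ± 1.21 FPKM (SD, n = 3; limma adjusted p = 0.708). Neither list was called (camera adjusted p = 0.265 and 0.163; adjusted over the list alone, 1 rose and 2 fell, and 2 rose and 0 fell). Of 13 replication-dependent histone genes, 2 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.791). *HIST1H4H* rose 12.1-fold, from 3.39 ± 0.638 to 41.1 ± 4.1 FPKM (SD, n = 3), *HIST1H2BD* rose 1.4-fold, *HIST1H2AC* and *HIST1H2BK* fell by 0.66 and 0.43, and *HIST1H1C*, the most abundant, was at 63.7 ± 3.56 and 91.1 ± 22.5 FPKM (SD, n = 3; limma adjusted p = 0.166). Calls were lost when single libraries were left out, *HIST1H2BD* for each except Ctrl replicates 2 and 3, *HIST1H2BK* for each except Ctrl replicate 3 and SMS2 replicate 2, and *HIST1H2AC* for each except SMS2 replicate 1, with limma adjusted p up to 0.121, 0.0741 and 0.133. The *KDR* call was lost without Ctrl replicate 2 or any SMS2 library (up to 0.0654). Among the genes named from the lists, the values of *DEPTOR*, *NOLC1*, *GNL3*, *RRP12*, *KRT19*, *COL6A3*, *AMBP*, *ELOVL6*, *IFI27*, *AREG*, *RPS9*, *HIST1H2BK*, *ASNS*, *TRIB3*, *S100A4*, *ADH1B* and *CD68* changed partners between files and are uncertain. Those of *CENPA*, *TM7SF2*, *NDUFA9* and *PDGFRA* were shared with other symbols in each file.

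Among stable loci, 12 of 25 glycolysis and hypoxia genes rose and 1 fell, as did 14 and 1 of 25 mesenchymal, 15 and 4 of 24 NF-kB, 10 and 1 of 18 interferon-stimulated, 20 and 1 of 40 G1/S, 17 and 3 of 36 G2/M and 10 and 2 of 18 cholesterol synthesis genes. Of 52 ribosomal protein genes 32 fell and 0 rose, of 33 oxidative phosphorylation genes 15 fell and 2 rose, and of 20 hepatocyte genes 6 fell and 2 rose. Of these lists, cholesterol synthesis alone was not called among stable loci.

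**Figure D3:**
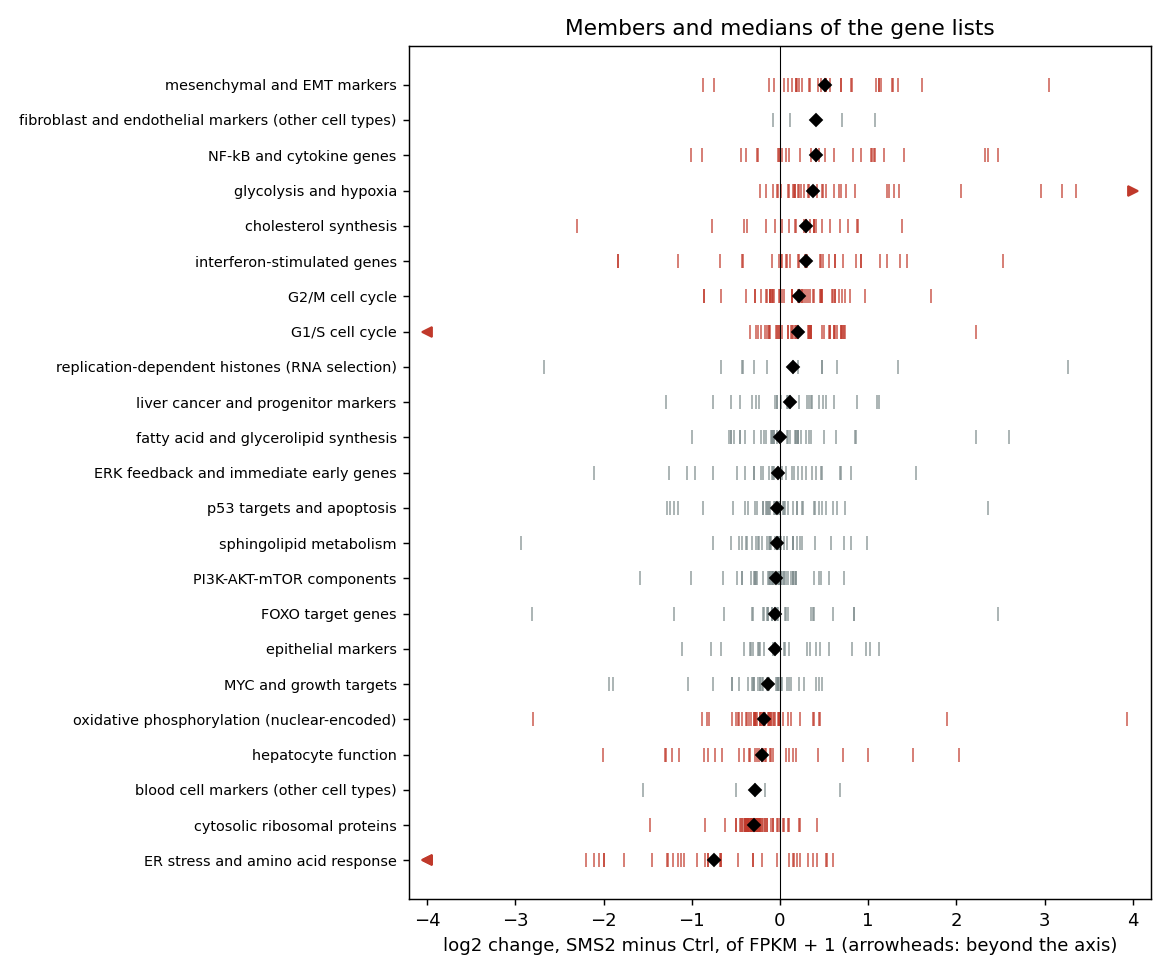
Log2 change (SMS2 minus Ctrl, of FPKM + 1) of the members of 23 gene lists; ticks are genes, diamonds are list medians, arrowheads are genes beyond the axis, and red marks lists called by camera at an adjusted p of 0.05. In the main test shown, the ER stress and amino acid response list had the lowest median (-0.74) and the mesenchymal list the highest (0.51). Among stable loci the mesenchymal median was 0.335, and not the highest: that of 5 replication-dependent histone genes was 0.472 and that of NF-kB genes 0.426.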

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

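*SGMS2* kept its call under each alternative run, with log2 changes of 3.07 to 3.41. Of 2418 values of the other named genes under alternatives, 2261 kept their call, 153 lost it, 4 gained one and 0 reversed; 89 of 111 called genes besides *SGMS2* kept the call without each library in turn. The count of genes was 2234 to 3327 when 1 library was left out (1085 to 1608 higher, 1149 to 1719 lower). These fits have fewer degrees of freedom than the main test. With a change of at least 1 on the log2(FPKM + 1) scale it was 439 (270 higher, 169 lower), and rescaling to a common sum gave 2747 higher and 1128 lower. The alternatives for stable loci, shared values and length and GC were chosen after the data were examined. The same replicate numbers did not pair the libraries (correlations of deviations 0.0162, -0.00785 and 0.0355, and not every library correlated best with its own number), and a replicate block, which leaves fewer degrees of freedom, gave 976 genes (461 higher, 515 lower). Of 231 values of the 11 called lists under alternatives other than another set test, 226 stayed past the threshold. Cholesterol synthesis was not called at a minimum of 5 FPKM (adjusted p = 0.0505) or among stable loci (0.0593), and ranged from 0.0065 to 0.066 when 1 library was left out; oxidative phosphorylation was not called under quantile normalization (0.107). With an estimated inter-gene correlation 0 lists were called: adjusted p was 0.525 for G1/S, 0.457 for cholesterol synthesis, 0.266 for NF-kB, and 0.176 for G2/M, mesenchymal, hepatocyte, glycolysis and hypoxia, ER stress, interferon, oxidative phosphorylation and ribosomal lists. That setting also tests on fewer degrees of freedom, so a lost call need not come from correlated members. The estimated correlation was 0.265 for G1/S and 0.126 for ribosomal protein genes. It was -0.000141 for G2/M and -0.0188 for interferon-stimulated genes, below the preset 0.01, and these calls were lost as well. MYC targets were called with no filter (0.0211) and liver cancer markers under quantile normalization (0.0224). fry, which asks only whether members move one way, did not call G1/S (0.152) and also called PI3K-AKT-mTOR (0.0332), FOXO (0.0226), MYC (0.0226), liver cancer (0.000175), ERK (0.0108), blood (0.0332) and fibroblast and endothelial (0.000232) lists. The direction of 5 uncalled lists changed in some setting. The cause of these changes was not tested. Depth is unknown, so changes near the floor cannot be bounded.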

Other observations

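The tests on added gene lists, on unlisted symbols and shared values, on the arms of the stress list, on batch, on other splits of the libraries, and on oxidative phosphorylation and G2/M with other scalings or without length and GC trends were chosen after the result was seen; the tests of scaling and of length and GC on the stress and ribosomal lists were written before their results were seen, those on the ribosomal list for a wider pattern that was narrowed to that list afterwards. Of 25 NRF2 targets, 20 were lower and 0 higher (median log2 change -0.49; camera adjusted over 8 added lists, adjusted p = 2.08e-10; adjusted p = 0.0359 with an estimated correlation). Among stable loci 10 of 13 fell and 0 rose, with a median log2 change of -0.318. *OSGIN1* fell by 1.74, *HMOX1* by 0.65 and *GCLC* by 0.63 on the log2 scale. Heat shock genes were higher, with 12 of 17 risen and 1 fallen (adjusted p = 3.67e-07; 0.0758 with an estimated correlation): *HSPA8* rose by 1.42 and *HSP90AA1* by 1.10, and *CRYAB* fell by 1.37. In the 12 and the 17, *HSPA1A* and *HSPA1B* each count, though they had the same values and are 1 measurement. Among stable loci, where it counts 1 time, 9 of 12 rose and 1 fell. Genes of COPII transport and ER export were higher, with 10 of 21 risen and 2 fallen (adjusted p = 0.000281; 0.0374 with an estimated correlation), and 9 risen and 2 fallen of 16 stable loci. *SEC24D* rose by 1.60 and *LMAN1* by 0.82, while *SAR1B* fell by 2.01 on the log2 scale. These example genes were chosen after their values were seen, and *OSGIN1* and *HSPA8* changed partners between files and are uncertain. Lysosome and autophagy genes had 11 fallen and 1 risen of 34 (adjusted p = 0.0062; 0.292 with an estimated correlation), and 9 fallen and 1 risen of 25 stable loci. TGF-beta response genes (adjusted p = 0.461) and aldo-keto genes (0.119, with a median below 0 and a mean above) were not called. Metallothioneins had too few tested members for the list test, and both of these, *MT1X* and *MT2A*, rose by 3.91 and 1.20 on the log2 scale.

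Of 439 symbols called with a change of at least 1 on the log2(FPKM + 1) scale, 111 were not listed in every file and 102 changed partners. The naming of loci may account for such changes: of 1044 symbols that had a partner's value in some files of 1 group and not in others, 49.5% (exact binomial interval 46.4% to 52.6%) jumped by at least 1 on that scale at the switch within that group, against 3.7% of 8047 stable loci (largest difference of any library from the others of its group). Over 38 pairs that shared a value in 2 to 5 files, the partner moved by a median 0.217 of the called symbol's change (bootstrap interval 0.0936 to 0.454), though these symbols were picked for a large change. For unlisted symbols a loss of expression in 1 group cannot be told apart from naming: of 76 symbols at 20 FPKM or more wherever listed and missing from exactly 3 files, 24 (31.6%, exact binomial interval 21.4% to 43.3%) were missing by group, against 10% by chance, and *DDIT3* is among the genes left open. The reading depends on the symbols counted: over all 275 missing from 1 to 3 files, the share first used, it was 8.73% (5.67% to 12.7%), which argued against a loss, but symbols missing from fewer than 3 files cannot be missing by group. Naming that differs between the groups would also exceed the 10%. Symbols with shared values were not merged in these counts. *GON4L* and *YY1AP1*, which are 1 measurement, both count among the 24, so the intervals may be too narrow. Among stable loci, 0 were at 20 FPKM or more in each file of 1 group and under 1 in each of the other. A gene without any reads in 1 group would be unlisted there and not a stable locus, so full losses stay untested.

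The fall of the ER stress and amino acid response list was compared between scalings. A constant factor per library moves a list and all genes nearly alike, so only quantile normalization could test scaling. Under it the list median relative to that of all genes was -0.642, against -0.744 in the main test. That argues against scaling of this kind as the whole reason. Length and GC as the whole reason are argued against too, since the list stayed called with those trends removed (camera adjusted p = 1.70e-05). Of the 38 members of that list 8 rose, and 6 of 28 among stable loci. A rise of ER chaperone genes as a group was not shown: of 21 such genes 8 rose and 2 fell, camera did not call them (adjusted p = 0.0528; 0.14 with an estimated correlation), and 6 of the 8 had been seen to rise in the planned list before the arm was written, while of 6 members outside that list 2 rose and 0 fell. Of 33 ATF4-arm genes 28 were called lower and 1 rose (21 and 1 of 25 stable loci). The 28 include *DDIT3*, which was not listed in the SMS2 libraries and is left open between loss and naming. But 19 of the 33 are members of the planned list, whose fall had been seen. Of the other 14, 12 fell and 0 rose. The arm was written after the data were examined, and *SLC6A9* and *PCK2*, among the 12, are also among the largest falls given above. These counts are therefore not independent support. A culture, library or sequencing batch cannot be told apart from SMS2, since the headers of 3 of 3 control libraries carry a tag that 0 SMS2 headers carry, so a lower amino acid response may come from SMS2 or from cultures handled differently, and neither was tested.

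Ribosomal protein and oxidative phosphorylation genes were lower while cell cycle and mesenchymal genes were higher, and log2 changes rose with transcript length across 7161 stable loci (Spearman rho 0.142, and -0.186 with GC). Length and GC as the whole reason for the ribosomal fall are argued against, since the list stayed called with the trends removed (camera adjusted p = 1.38e-07, median -0.21). Camera compares a list with other genes, so a constant factor per library could hardly undo the call. Only quantile normalization could test scaling. Under it the list stayed called (camera adjusted p = 0.00102), but its median relative to all genes shrank from -0.29 to -0.13. Scaling may thus account for part of the ribosomal fall. With an estimated correlation the ribosomal list was not called (camera adjusted p = 0.176). Length and GC as the whole reason are also argued against, narrowly, for oxidative phosphorylation, whose median relative to all genes went from -0.206 to -0.141 over the same 43 genes (bootstrap interval -0.202 to -0.0546), and for G2/M, which went from 0.21 to 0.0925 (0.0166 to 0.288), both at an adjusted p of 0.049 with members resampled as if independent, so length and GC may account for much of the G2/M rise. Scaling stays open for oxidative phosphorylation, which was not called under quantile normalization (0.107), as do batch and a response to SMS2, which was not tested, for all these lists. For the count of changed genes, 3 against 3 libraries make 10 splits, too few for a share under 0.05: 1 split, the real one, gave 3718 genes, and the highest other gave 28.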
